A study of Nicotiana tabacum with 6 samples.

How the data were processed

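RNA sequencing was done on leaves of the tobacco (Nicotiana tabacum) line GDH64 and of MuGDH64, a line derived from it by gamma irradiation, with 3 libraries of each. Per the labels' protocols, total RNA was taken with TRIzol and treated with DNase I, TruSeq RNA libraries were made, and paired-end reads came from an Illumina NovaSeq X instrument. The submitters' processing notes name TopHat2, a spliced read aligner, and Cufflinks, a transcript quantifier, without versions, roles or settings. The genome build and the annotation are not given in the sources used here. The gene identifiers follow the Nitab4.5 gene models, and each row carries a text of protein domain names but no gene symbol.

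The deposited file is 1 table of 69500 gene models with a value for each of the 6 libraries and the authors' mean for each line. The file header names no unit. The deposited values were taken as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), by inference: they are not whole numbers, they sum to between 634425 and 756316 per library, and Cufflinks is a tool that reports FPKM. Columns were matched to samples by the library names in the labels. The authors' means were checked to equal the means of the 3 library columns and were not used further. The steps between low values did not recover whole reads, so the sequencing depth of each library is unknown and no counting error could be given. An FPKM scaling assumes that the libraries hold comparable totals of RNA, and it does not correct for a few abundant transcripts that take a larger share of one library.

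Because the table holds no counts, no count model was used. Values were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the mean-variance trend, on the 32340 gene models with at least 1 FPKM in at least 3 libraries. The model held the line only, the tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. A fold change is therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. The labels describe a field layout in randomized blocks with 3 replicates and pooled leaf punches of 3 plants per plot, taken at several dates in more than 1 season. No label ties a library to a date or a season, or a library number to a block. The p values measure the spread between these 3 and 3 libraries.

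Gene lists for pathways, cell types and stress responses were written as text patterns before the data were examined. Of these 38 lists, 7 matched no row because the table gives domain names in place of protein names, and 30 had at least 5 tested members. A further 44 lists of protein domains were written after the descriptions and the values of the most abundant genes had been seen, and before any test was run; 42 of them were tested. Lists were compared with all other genes by camera from limma with a preset correlation between genes of 0.01, and adjusted within each family of lists. The same test with a correlation estimated from the data, and fry, which asks whether a list moves on balance in one direction, were run as alternatives. The genes named in the text are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose 3 MuGDH64 values all lay on one side of the 3 GDH64 values, whose mean in the higher line was at least 5 FPKM and whose description was not unknown, plus up to 3 members with the smallest adjusted p of each list. The rule would also have named every member of a list for NtCYC and the cembranoid pathway. No description matched that list and no table linked the gene models to names, so NtCYC itself was not analysed here; the terpene synthase family, to which cembratrienol cyclases belong, was.

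The alternatives planned before the data were examined were quantile normalization, limma without the trend, no filter on low values, a filter of 5 FPKM, a pseudocount of 0.1, values rescaled to a sum of 1000000, the library number as a block, and each library left out in turn. Median-centring and library weights were added after the data had been seen. The procedure was tested on simulated data with the spread of the 32340 tested genes and 200 genes changed by known amounts: 14.9% of the genes changed 1.5-fold, 71.6% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, and 7 of the 124 calls were false. In 200 random lists of 30 genes without a change, 2% had a camera p under the threshold. The simulated genes were drawn independently of each other, so this share does not test the preset correlation between genes. The simulation held 200 changed genes and no shift between the lines. The data gave 3863 calls and a median log2 fold change of -0.176, so the shares recovered and the false calls need not hold for them. Tables, permutations and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.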

Results

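Leaf transcripts of the flue-cured tobacco line GDH64 were compared with those of MuGDH64, an aphid-resistant line obtained from it by cobalt gamma irradiation. The title of the series names a mutation of NtCYC, a gene of cembranoid synthesis in glandular trichomes, together with trichome density and aroma. Each line had 3 RNA sequencing libraries of leaf, and no label says from which sampling date they came. The table held FPKM values for 69500 gene models, of which 19827 (28.5%) had no described domain. Summed FPKM was 751469, 756316 and 728572 in the GDH64 libraries and 719776, 705239 and 634425 in the MuGDH64 libraries. The number of models with at least 1 FPKM was 32171, 32641 and 31998 against 31626, 31463 and 31018. The read depth is unknown. Across the 32340 tested genes, which are not independent replicates, Pearson's r lay between 0.9686 and 0.9795 for libraries of one line and between 0.9474 and 0.9615 for libraries of different lines. The first principal component held 50.3% of the variance and parted the lines. On it the 2nd GDH64 library, at -53.63, lay apart from the other GDH64 libraries at -30.62 and -25.61, and the MuGDH64 libraries lay at 30.46, 33.67 and 45.74.

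The question of the comparison was which leaf genes differed between the irradiated line and its parent. In MuGDH64 a heat shock protein 90 chaperone, Nitab4.5_0000152g0350, rose from 10.5 ± 0.656 to 155 ± 4.14 FPKM (mean ± SD, n = 3 libraries per line, as in all values that follow; limma adjusted p = 3.97e-07). A protein with the ribosomal L2 fold, Nitab4.5_0000720g0040, fell from 244 ± 13.4 to 9.66 ± 2.72 FPKM (adjusted p = 6.3e-06). A terpene synthase, Nitab4.5_0005904g0070, of the enzyme family that forms the carbon skeletons of mono-, sesqui- and diterpenes, rose from 5.80 ± 0.433 to 44.8 ± 8.92 FPKM (adjusted p = 2.75e-05). A WRKY transcription factor, Nitab4.5_0000508g0130, stood at 16.57, 14.2 and 22.21 FPKM in GDH64 and was listed at 0 in each MuGDH64 library.

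In total 3863 genes passed the limma test, 712 higher and 3151 lower in MuGDH64, and 644 of them differed at least 2-fold (248 higher and 396 lower). On the deposited values the lines did not overlap for 12130 genes (37.5%, where chance gives 10%). A shift between the lines as a whole can add to this count, which was not repeated after quantile normalization. The median log2 fold change of all tested genes was -0.176. Log2 changes below are therefore given relative to this median, on the log2(FPKM + 1) scale, while adjusted p values belong to the changes before this subtraction. After quantile normalization 3104 genes passed, 1433 higher and 1671 lower, and 2364 of the 3863 genes passed again with the same sign. The excess of lower genes depended on the scaling. Higher genes made up 18.4% of the calls as deposited, 46.2% after quantile normalization and 58.4% after median-centring, which was chosen after the shift had been seen. Counts were smaller without GDH64 library 1 (1794 genes, 449 higher and 1345 lower), without GDH64 library 2 (1939 genes, 1445 lower) and without MuGDH64 library 1 (2571 genes, 356 higher). The same held without MuGDH64 library 2 (2028 genes, 348 higher and 1680 lower) and without MuGDH64 library 3 (1854 genes, 1363 lower).

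Among the other genes with the largest rise, a cyclophilin-type peptidyl-prolyl isomerase, Nitab4.5_0001150g0020, rose from 0.813 ± 0.223 to 20.7 ± 4.001 FPKM. A PTPLA protein, Nitab4.5_0000902g0360, of the family that holds a dehydratase of very-long-chain fatty acid elongation, rose from 0.453 ± 0.155 to 12.3 ± 0.357 FPKM. A pair of transferases with a chloramphenicol acetyltransferase-like fold, the fold of plant BAHD acyltransferases, rose as well. Of these Nitab4.5_0011112g0010 went from 0.537 ± 0.367 to 10.6 ± 1.08 FPKM and Nitab4.5_0013262g0010 from 0.543 ± 0.155 to 8.48 ± 0.747 FPKM. An EF-hand and dynamin-type GTPase, Nitab4.5_0000984g0060, rose by 2.86, an ascorbate peroxidase, Nitab4.5_0000209g0170, by 2.85, a GATA zinc finger factor, Nitab4.5_0000147g0030, by 2.82 and a chloride channel, Nitab4.5_0001220g0060, by 2.70 on the relative log2 scale. An RNA recognition motif protein, Nitab4.5_0000068g0480, was listed at 0 in each GDH64 library and stood at 10.12, 8.49 and 7.16 FPKM in MuGDH64. A saccharopine dehydrogenase or homospermidine synthase, Nitab4.5_0000565g0040, stood at 0, 0 and 0.04 FPKM in GDH64 and at 24.27, 13.68 and 2.63 FPKM in MuGDH64.

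Among the genes with the largest fall, a SecE/Sec61-gamma subunit of the protein translocation channel, Nitab4.5_0000043g0080, stood at 18.25, 14.39 and 13.56 FPKM in GDH64 and was listed at 0 in all 3 MuGDH64 libraries. The same held for a peptide methionine sulfoxide reductase, Nitab4.5_0000510g0010 (5.06, 25.38 and 12.41 FPKM in GDH64), and for a GRF-type zinc finger protein, Nitab4.5_0004720g0040 (5.41, 13.01 and 2.28 FPKM). An armadillo repeat protein, Nitab4.5_0000465g0060, fell from 18.2 ± 1.63 to 0.33 ± 0.321 FPKM and a GRAS transcription factor, Nitab4.5_0025058g0010, from 23.7 ± 2.35 to 1.75 ± 0.505 FPKM. An NB-ARC protein of the resistance receptor family, Nitab4.5_0001553g0040, fell from 10.7 ± 0.702 to 0.567 ± 0.186 FPKM. A K homology domain protein, Nitab4.5_0000359g0220, stood at 21.57, 22.56 and 19.89 FPKM in GDH64 and at 1.65, 2.31 and 0 FPKM in MuGDH64. An NnrU protein, Nitab4.5_0006519g0030, fell by 2.86, a cation efflux protein, Nitab4.5_0000598g0050, fell by 2.59 and a UDP-glycosyltransferase, Nitab4.5_0001649g0040, fell by 2.55 on the relative log2 scale. Adjusted p of these 24 most changed genes ran from 3.97e-07 to 0.0087. All 24 passed with the same sign after quantile normalization. In the fits without 1 library, each of them that still met the filter passed with the same sign. A gene with at least 1 FPKM in only 3 libraries could not be tested once 1 of these was left out. Tobacco is an allotetraploid, so reads of near-identical copies may have been shared or split between gene models, and a value of 0 can be a failed estimate.

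**Figure D1:**
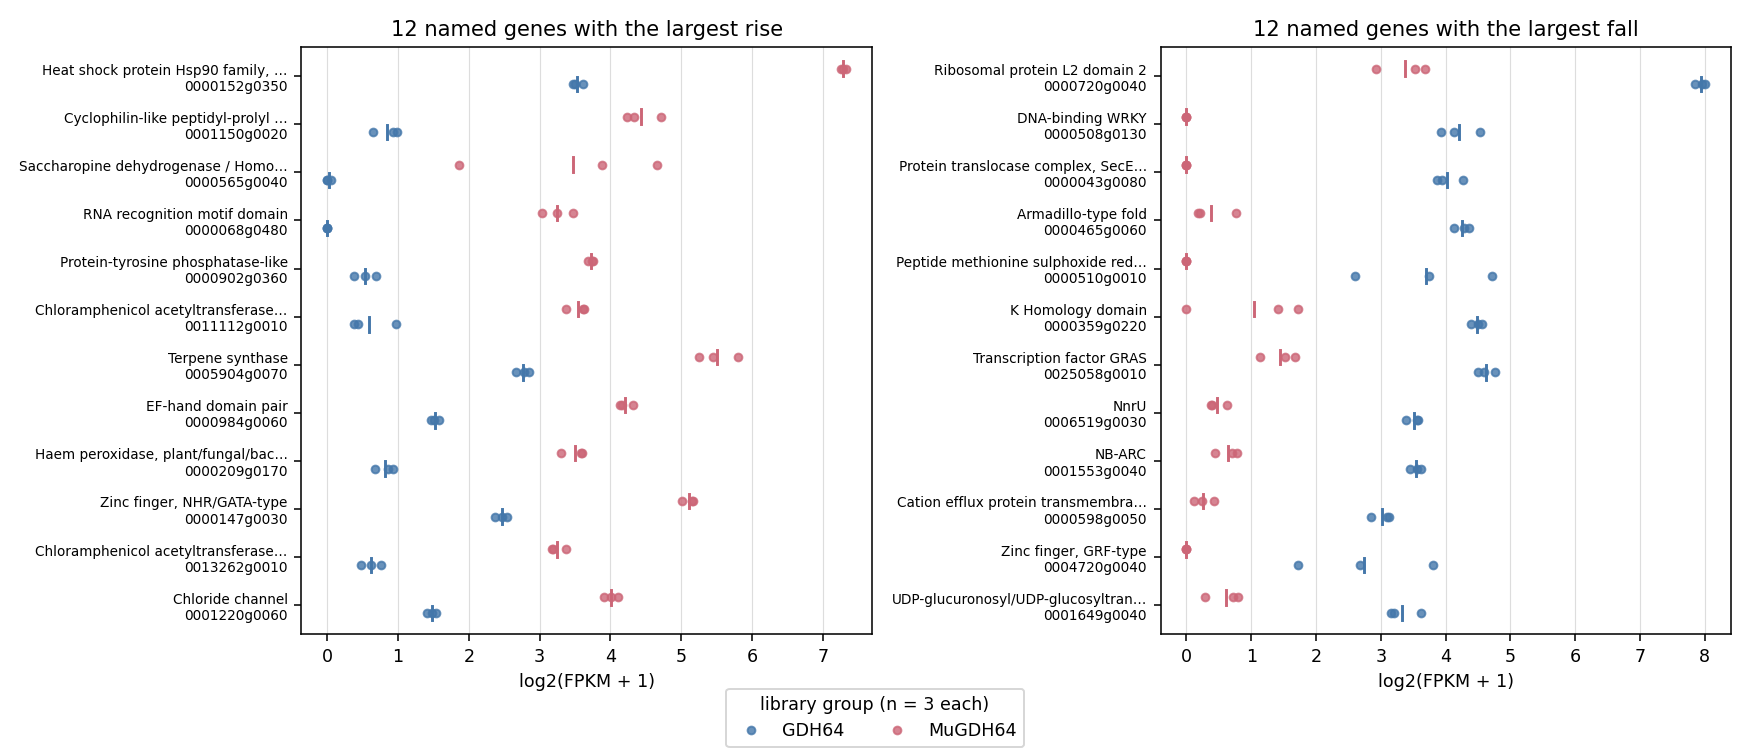
Values of the 24 most changed named genes as log2(FPKM + 1) on the horizontal axis, 1 point per library (GDH64 blue, MuGDH64 red, n = 3 each) with vertical bars at the mean of each line. The Hsp90 gene at the top left moved from 10.5 to 155 FPKM, the ribosomal L2-fold gene at the top right from 244 to 9.66 FPKM, and the libraries of the lines do not overlap for any gene shown.

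Terpene synthase genes lay above the other genes in MuGDH64, with members moving both ways. Beside Nitab4.5_0005904g0070, a terpene synthase with few transcripts in GDH64, Nitab4.5_0002485g0030, rose from 1.44 ± 0.258 to 12.2 ± 2.35 FPKM (adjusted p = 8.69e-05). Another, Nitab4.5_0003738g0070, fell from 9.003 ± 0.0451 to 1.02 ± 0.0436 FPKM (adjusted p = 1.99e-05). The list fixed beforehand had 59 measured members, among them prenyl diphosphate synthases, squalene/phytoene synthases and squalene cyclases, 1 of which fell. Of the 59 members 12 rose and 8 fell (16 and 9 adjusted over the list alone, 17 and 6 after quantile normalization). The list passed camera with a preset correlation (adjusted p = 2.24e-05, median 0.178 above all genes), but not with one estimated from the data (adjusted p = 0.978 with an estimated correlation). The list also passed in each of 15 other settings, which changed 1 step of the processing or left out 1 library (adjusted p at most 0.00563). Of these settings 2 were chosen after the data had been seen. The tallies of settings here and below leave out the estimated correlation and fry. By fry the terpene synthase list did not pass either (fry adjusted p = 0.169). Among the 37 proteins with a terpene synthase domain, squalene cyclases included, 9 rose and 6 fell, against 10 and 4 after quantile normalization (camera adjusted p = 1.75e-04; adjusted p = 0.696 with an estimated correlation). Among the 15 polyprenyl synthetases, which join isoprene units into prenyl diphosphates, 3 rose and 2 fell, against 6 and 2 after quantile normalization (camera adjusted p = 0.00301; adjusted p = 0.696 with an estimated correlation). One of them, Nitab4.5_0003328g0080, rose from 6.43 ± 0.424 to 11.5 ± 0.800 FPKM. The domain names do not say which product an enzyme makes, and NtCYC itself was not analysed here.

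**Figure D2:**
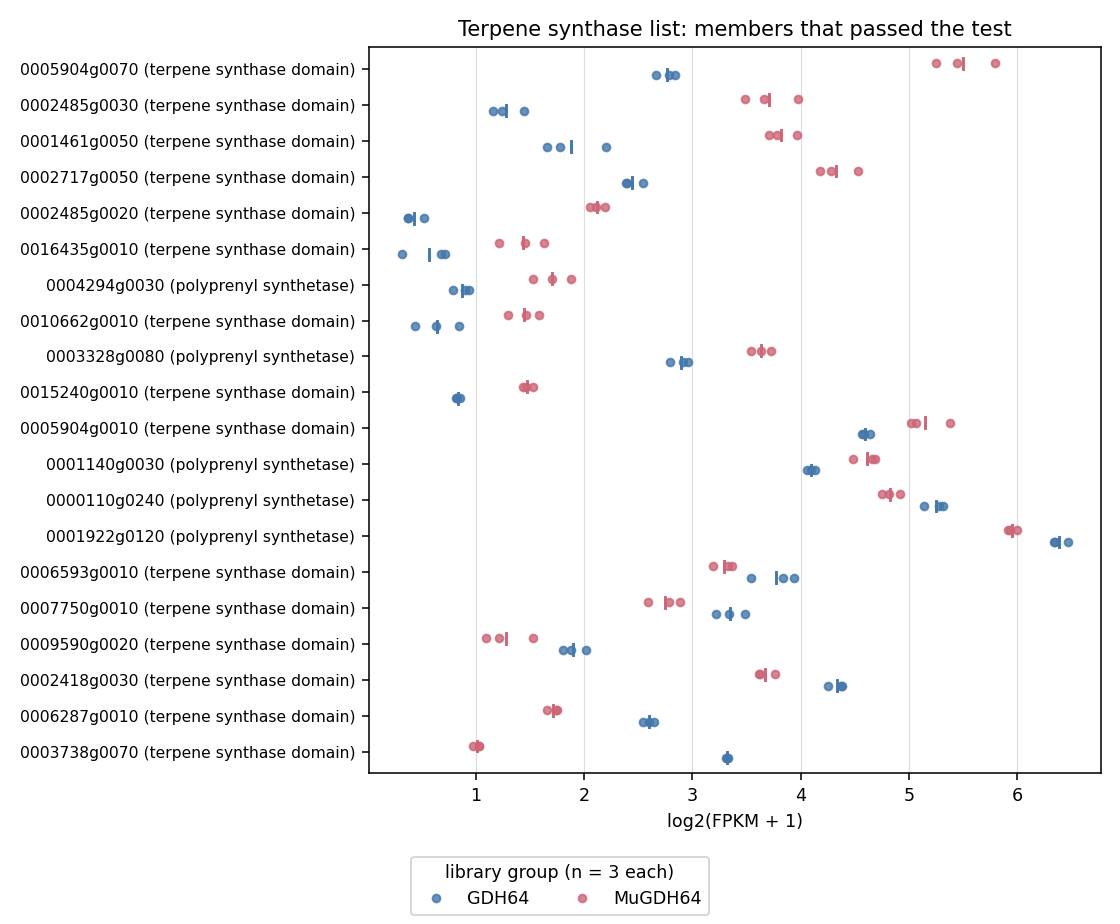
The 20 members of the terpene synthase list that passed the test, as log2(FPKM + 1) on the horizontal axis, 1 point per library (GDH64 blue, MuGDH64 red, n = 3 each) with vertical bars at the mean of each line. As deposited 12 members lie higher and 8 lower in MuGDH64, and among all 59 members the counts are 17 and 6 after quantile normalization.

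Genes that supply isoprene units also lay above the other genes. A hydroxymethylglutaryl-CoA reductase, Nitab4.5_0000235g0130, the rate-limiting step of the mevalonate pathway, rose from 13.98 ± 1.06 to 28.8 ± 2.92 FPKM (adjusted p = 0.00158). It was the 1 gene of 19 in the mevalonate list to pass (1 also adjusted over the list alone), against 3 higher and 0 lower after quantile normalization. In the plastid methylerythritol phosphate list 2 of 14 genes rose and none fell (2 and 1 adjusted over the list alone, 3 and 0 after quantile normalization). Both genes that rose as deposited are described as isopentenyl diphosphate isomerases, and no other enzyme of the list was called higher there. One of them, Nitab4.5_0000971g0070, rose from 5.29 ± 1.32 to 9.98 ± 1.68 FPKM (adjusted p = 0.0245). It passed in 12 of 15 other settings (adjusted p from 0.0104 to 0.0688), but not without MuGDH64 library 1 (0.0688) or MuGDH64 library 3 (0.06). Camera gave an adjusted p of 0.0196 for the plastid list and 0.0174 for the mevalonate list (adjusted p = 0.978 for both with an estimated correlation). Each passed in 14 of 15 other settings, the plastid list missing without the filter (adjusted p = 0.0535) and the mevalonate list without GDH64 library 1 (adjusted p = 0.0612). Neither passed fry (fry adjusted p = 0.602 for the plastid list and 0.625 for the mevalonate list).

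Cytochrome P450 genes changed in both directions, with 21 of 212 higher and 36 lower as deposited and 32 higher and 20 lower after quantile normalization. Nitab4.5_0013195g0010 rose from 20.4 ± 3.48 to 58.01 ± 5.29 FPKM and Nitab4.5_0007569g0010 from 8.68 ± 0.423 to 21.7 ± 1.27 FPKM, while Nitab4.5_0000027g0190 fell from 6.72 ± 0.578 to 1.97 ± 0.275 FPKM. As a list they passed camera above the other genes with an adjusted p of 0.0356 (adjusted p = 0.732 with an estimated correlation). The list passed in only 6 of 15 other settings (adjusted p from 0.0139 to 0.35). It missed the threshold after quantile normalization (0.203) and without GDH64 library 2 (0.0655) or MuGDH64 library 1, 2 or 3 (0.144, 0.134 and 0.309).

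The domain lists of fatty acid elongation and wax genes, homeobox START proteins and ABC-2 transporters lay below the other genes, while no test tied their members to the leaf surface. The 3-ketoacyl-CoA synthases Nitab4.5_0017907g0010, Nitab4.5_0005199g0070 and Nitab4.5_0000391g0350, which extend fatty acids for cuticular wax, fell from 68.96 ± 7.28 to 32.1 ± 2.96, from 49.9 ± 1.13 to 30.3 ± 2.60 and from 49.7 ± 3.31 to 27.7 ± 3.74 FPKM. Of 28 very-long-chain fatty acid elongation and wax genes 14 fell and none rose, against 9 and 0 after quantile normalization (camera adjusted p = 0.00551; adjusted p = 0.696 with an estimated correlation). The list was drawn from 3-ketoacyl-CoA synthase and Wax2 domains and leaves out the PTPLA protein Nitab4.5_0000902g0360, which rose. The narrower list fixed beforehand had 11 of 23 genes lower and none higher (11 adjusted over the list alone) and missed the threshold as deposited (camera adjusted p = 0.182). It passed after quantile normalization (adjusted p = 0.0446) but not with an estimated correlation on the deposited values (adjusted p = 0.978 with an estimated correlation). Of 21 homeobox proteins with a START domain, a family that includes regulators of epidermis and trichomes, 7 fell and 1 rose (camera adjusted p = 0.0291; adjusted p = 0.696 with an estimated correlation). Among them Nitab4.5_0002347g0050 fell from 3.71 ± 0.145 to 1.36 ± 0.155 FPKM and Nitab4.5_0008369g0020 from 4.88 ± 0.473 to 2.15 ± 0.327 FPKM. Of 34 ABC-2 type transporters, a class that includes exporters of wax and terpenoids, 8 fell and none rose, against 5 and 0 after quantile normalization (camera adjusted p = 0.00562; adjusted p = 0.696 with an estimated correlation). One of them, Nitab4.5_0002451g0040, fell from 12.2 ± 0.537 to 7.08 ± 1.08 FPKM. Lipid transfer proteins had 2 higher and 4 lower of 25 (camera adjusted p = 0.598), with Nitab4.5_0001059g0030 lower at 8.59 ± 0.734 against 21.3 ± 2.65 FPKM. The wax elongation list passed in 14 of 15 other settings and the transporter list in 13, with the highest adjusted p without the filter (0.446 and 0.499). The homeobox list passed in 9 of 14, and missed without GDH64 library 2 (0.0505), GDH64 library 3 (0.062) or MuGDH64 library 1 (0.0922).

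The auxin list lay below the other genes, with most of its members not past the threshold. The auxin efflux carriers Nitab4.5_0004944g0030 and Nitab4.5_0000495g0070 fell from 37.5 ± 3.58 to 13.2 ± 1.59 and from 63.1 ± 4.27 to 28.1 ± 1.99 FPKM. An ARG7-type auxin-induced gene, Nitab4.5_0000747g0050, fell from 79.6 ± 8.13 to 32.7 ± 2.11 FPKM. Of 96 auxin genes 24 fell and 1 rose (33 and 2 adjusted over the list alone), against 14 lower and 3 higher after quantile normalization (camera adjusted p = 0.00191; adjusted p = 0.978 with an estimated correlation). It passed in 14 of 15 other settings, and missed without the filter (adjusted p = 0.249). In the gibberellin and cytokinin list 2 of 30 genes rose and 6 fell as deposited (2 and 10 adjusted over the list alone), against 4 and 1 after quantile normalization (camera adjusted p = 0.486). A gibberellin-regulated protein, Nitab4.5_0002978g0140, fell from 90.6 ± 9.88 to 28.4 ± 1.58 FPKM (adjusted p = 8.65e-05). The cytokinin-activating phosphoribohydrolases Nitab4.5_0001297g0040 and Nitab4.5_0001192g0070 rose from 20.4 ± 3.14 to 44.99 ± 4.11 and from 56.6 ± 11.4 to 107 ± 11.1 FPKM. Of 74 abscisic acid and late embryogenesis abundant genes 18 fell and none rose (21 and 1 adjusted over the list alone, 12 and 0 after quantile normalization; camera adjusted p = 0.486), with Nitab4.5_0000116g0500 lower at 277 ± 22.6 against 510.0 ± 23.6 FPKM. In the jasmonate list 1 of 18 genes rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.655). The lipoxygenase Nitab4.5_0002164g0020 fell from 25.3 ± 3.12 to 14.96 ± 0.637 FPKM and the lipoxygenase Nitab4.5_0000043g0340 rose from 8.63 ± 1.01 to 13.97 ± 0.429 FPKM. The ethylene list had 1 of 6 genes lower (2 adjusted over the list alone; camera adjusted p = 0.764).

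AP2/ERF transcription factors, which act in ethylene and stress responses, lay below the other genes as a list. Nitab4.5_0002236g0020 fell from 182 ± 19.2 to 82.3 ± 6.56 FPKM and Nitab4.5_0002289g0130 from 9.70 ± 0.595 to 3.21 ± 0.252 FPKM. Of 180 members 46 fell and 3 rose, against 33 and 3 after quantile normalization (camera adjusted p = 0.00587; adjusted p = 0.713 with an estimated correlation). The list passed in 13 of 15 other settings, and missed without the filter (0.277) and without GDH64 library 3 (0.0526). Proteins with a CCT domain, which include B-box regulators of light signalling and flowering time, formed a list with the clock protein GIGANTEA. The CCT protein Nitab4.5_0000935g0190 fell from 15.7 ± 0.870 to 9.44 ± 0.481 FPKM and the B-box protein Nitab4.5_0013324g0010 from 38.7 ± 3.17 to 24.5 ± 2.22 FPKM. In this list 20 of 45 genes fell and 1 rose, against 13 and 1 after quantile normalization (camera adjusted p = 3.49e-05; adjusted p = 0.696 with an estimated correlation). The member that rose, a GIGANTEA model, Nitab4.5_0004270g0010, went from 8.10 ± 0.415 to 11.04 ± 0.269 FPKM (adjusted p = 0.0369). It lost its call in each fit without 1 library, at adjusted p from 0.0773 to 0.113. WRKY factors had 9 higher and 13 lower of 102 as deposited and 12 higher and 9 lower after quantile normalization (camera adjusted p = 0.0505). NAC factors had 1 higher and 11 lower of 76 (camera adjusted p = 0.961). MADS-box genes had 2 higher and 6 lower of 40 as deposited and 3 and 2 after quantile normalization. Their list passed above the other genes (camera adjusted p = 0.0412; adjusted p = 0.696 with an estimated correlation). It passed in only 6 of 15 other settings (adjusted p from 0.013 to 0.854). It missed after quantile normalization (0.219) and without GDH64 library 2 (0.0583), GDH64 library 3 (0.236), MuGDH64 library 1 (0.213) or MuGDH64 library 3 (0.145).

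Among chitinases, which hydrolyse chitin, the family 19 enzymes Nitab4.5_0003207g0080 and Nitab4.5_0001581g0010 rose from 128 ± 6.68 to 537 ± 107 and from 366 ± 33.9 to 893 ± 157 FPKM. Of 23 members 7 rose and 1 fell, against 9 and 7 adjusted over the list alone (camera adjusted p = 1.75e-04; adjusted p = 0.696 with an estimated correlation). Polyphenol oxidases, which brown wounded tissue, were lower, with a median log2 change of -1.085 relative to all genes. Among them Nitab4.5_0002482g0070 fell from 29.99 ± 1.89 to 11.9 ± 0.212 FPKM, Nitab4.5_0002200g0010 from 25.7 ± 2.40 to 8.20 ± 1.75 FPKM and Nitab4.5_0006480g0020 from 14.2 ± 5.21 to 1.86 ± 0.470 FPKM. Of 7 members 6 fell and none rose (camera adjusted p = 9.07e-04; adjusted p = 0.696 with an estimated correlation). CAP domain proteins, the family of PR-1, had 2 higher and 1 lower of 13 (camera adjusted p = 9.07e-04; adjusted p = 0.696 with an estimated correlation), with Nitab4.5_0004861g0030 up from 240.0 ± 43.9 to 417 ± 60.4 FPKM. The thaumatins Nitab4.5_0000360g0100 and Nitab4.5_0004097g0050 rose from 62.05 ± 6.598 to 298.5 ± 56.6 and from 151 ± 16.01 to 276.5 ± 31.6 FPKM, and Nitab4.5_0000864g0110 fell from 5.41 ± 0.478 to 2.18 ± 0.337 FPKM. Their pathogenesis-related list had 4 of 20 higher and 3 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.486). Bet v I proteins had 4 higher and 4 lower of 22 (camera adjusted p = 0.00551; adjusted p = 0.696 with an estimated correlation). Their list passed in 13 of 15 other settings and missed after quantile normalization (0.12). Of these proteins Nitab4.5_0008779g0030 rose from 0.203 ± 0.196 to 4.07 ± 1.53 FPKM and Nitab4.5_0009910g0010 fell from 7.79 ± 1.72 to 2.71 ± 0.354 FPKM.

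The fixed list of protease inhibitors, which also holds the polyphenol oxidases, did not differ from the other genes past the threshold (camera adjusted p = 0.582). Of 119 genes 4 were higher and 22 lower as deposited (4 and 23 adjusted over the list alone), against 8 and 14 after quantile normalization. A Kunitz inhibitor, Nitab4.5_0016396g0010, fell from 4.97 ± 0.871 to 0.76 ± 0.0872 FPKM and a potato inhibitor I protein, Nitab4.5_0000525g0290, from 594 ± 14.2 to 338 ± 40.0 FPKM. Of 179 immune receptor genes 4 rose and 15 fell (4 and 15 adjusted over the list alone; camera adjusted p = 0.934), against 5 and 6 after quantile normalization. On the scaffold that holds Nitab4.5_0001553g0040 another NB-ARC gene, Nitab4.5_0001553g0060, fell from 4.72 ± 0.396 to 0.743 ± 0.285 FPKM. Gamma thionins, the plant defensins, had 2 lower of 5 (camera adjusted p = 0.961), with Nitab4.5_0009181g0010 lower at 97.5 ± 10.03 against 186 ± 22.5 FPKM. Secretory peroxidases had 5 higher and 8 lower of 39 as deposited and 6 and 5 after quantile normalization (camera adjusted p = 0.586), with Nitab4.5_0000099g0090 lower at 6.97 ± 0.705 against 19.01 ± 2.37 FPKM. Papain-like proteases had 3 higher and 1 lower of 34 (camera adjusted p = 0.454).

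In phenolic metabolism, the phenylalanine ammonia-lyases Nitab4.5_0012382g0010 and Nitab4.5_0002130g0010, which open the phenylpropanoid pathway, fell from 5.80 ± 0.415 to 1.96 ± 0.657 and from 40.8 ± 6.47 to 25.2 ± 2.28 FPKM. Their list had 1 of 7 genes higher and 2 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.764). A chalcone isomerase of flavonoid synthesis, Nitab4.5_0000375g0270, rose from 1.12 ± 0.357 to 3.68 ± 0.903 FPKM. It was 1 of 2 higher genes among the 11 of the flavonoid list, where none fell (2 and 0 adjusted over the list alone, 3 and 0 after quantile normalization). That list passed camera above the other genes (adjusted p = 0.018; adjusted p = 0.978 with an estimated correlation). It passed in 10 of 15 other settings (adjusted p from 0.00559 to 0.0821), and missed after quantile normalization (0.0513) and without GDH64 library 1 (0.0612). UDP-glycosyltransferases had 10 higher and 28 lower of 125, against 9 and 18 after quantile normalization (camera adjusted p = 0.795), with Nitab4.5_0000037g0140 lower at 24.1 ± 2.47 against 77.5 ± 10.9 FPKM. In the nicotine list an ornithine decarboxylase-type enzyme, Nitab4.5_0003280g0010, fell from 13.4 ± 3.55 to 5.02 ± 0.472 FPKM. It was the 1 gene of 7 to pass (2 higher and 1 lower adjusted over the list alone and also after quantile normalization; camera adjusted p = 0.515).

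Nuclear photosynthesis genes lay above the other genes as a list of 127, which also catches plastocyanin-like proteins of other functions. By single genes 8 rose and 15 fell as deposited (13 and 20 adjusted over the list alone), and 16 rose and 8 fell after quantile normalization. The list passed camera (adjusted p = 0.00186; adjusted p = 0.978 with an estimated correlation). The light-harvesting proteins Nitab4.5_0000592g0360 and Nitab4.5_0002814g0030 fell from 34.5 ± 4.89 to 15.9 ± 2.33 and from 26.3 ± 1.51 to 12.97 ± 2.02 FPKM. Their family had 4 higher and 14 lower of 78 as deposited and 8 and 7 after quantile normalization (camera adjusted p = 0.454). Rubisco small subunits had no gene past the threshold among 8 as deposited and 2 higher after quantile normalization, and their list lay above the other genes (camera adjusted p = 0.00587; adjusted p = 0.696 with an estimated correlation), a call lost after quantile normalization (0.0957). Of 14 senescence genes 1 rose and none fell (1 adjusted over the list alone, 4 after quantile normalization). The list passed with a median 0.301 above all genes (camera adjusted p = 3.17e-04; adjusted p = 0.978 with an estimated correlation). The gene that rose, a pheophorbide a oxygenase type enzyme of chlorophyll breakdown, Nitab4.5_0003134g0120, went from 7.68 ± 0.501 to 11.7 ± 0.719 FPKM (adjusted p = 0.0156). It lost its call without GDH64 library 1 (0.0553), MuGDH64 library 2 (0.0611) or MuGDH64 library 3 (0.0507), and kept it in the other 12 settings. Chlorophyll synthesis had 1 of 25 genes lower (1 adjusted over the list alone; camera adjusted p = 0.486) and the carotenoid list 1 of 20 lower (1 adjusted over the list alone; camera adjusted p = 0.655), against 2 higher and 0 lower after quantile normalization.

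Sugar and water transporters lay below the other genes as lists. The SWEET sugar transporters Nitab4.5_0001332g0120 and Nitab4.5_0000633g0030 fell from 206 ± 21.4 to 127 ± 11.2 and from 30.3 ± 6.76 to 13.9 ± 1.59 FPKM. Of 30 members 14 fell and 2 rose, against 10 and 3 after quantile normalization (camera adjusted p = 0.0301; adjusted p = 0.713 with an estimated correlation). The list passed in 13 of 15 other settings, and missed without the trend (0.0609) and without GDH64 library 3 (0.0782). Of 48 aquaporins 17 fell and 3 rose, against 11 and 4 after quantile normalization (camera adjusted p = 0.0226; adjusted p = 0.723 with an estimated correlation), with Nitab4.5_0000956g0150 down from 16.1 ± 1.38 to 8.60 ± 0.774 FPKM. Their list passed in 11 of 15 other settings (adjusted p up to 0.0804), and missed without GDH64 library 3 (0.0526) or MuGDH64 library 1 (0.0546). A glutamine synthetase, which assimilates ammonium, Nitab4.5_0000574g0130, fell from 19.4 ± 0.830 to 5.24 ± 0.255 FPKM (adjusted p = 5.36e-05). In the nitrogen list 2 of 35 genes fell and none rose (2 adjusted over the list alone; camera adjusted p = 0.391). The carbohydrate list, which also holds SWEET genes and amylase inhibitors, had 4 of 82 higher and 18 lower (9 and 27 adjusted over the list alone; camera adjusted p = 0.582), against 10 and 12 after quantile normalization. Sucrose and starch enzymes had 4 higher and 3 lower of 68 as deposited and 11 and 2 after quantile normalization (camera adjusted p = 0.0795), with a family 32 glycosyl hydrolase, the family of invertases, Nitab4.5_0001295g0210, up from 9.60 ± 1.02 to 18.0 ± 0.894 FPKM. Oligopeptide and nitrate transporters had 4 higher and 15 lower of 83 (camera adjusted p = 0.853).

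Heat shock genes changed in both directions. The HSP70 chaperones Nitab4.5_0000015g0210 and Nitab4.5_0009965g0010 rose from 4.05 ± 0.518 to 12.02 ± 1.24 and from 2.28 ± 0.511 to 8.45 ± 1.08 FPKM. A small heat shock protein, Nitab4.5_0000319g0220, fell from 4.92 ± 1.63 to 0.25 ± 0.192 FPKM, and the abundant HSP90 gene Nitab4.5_0000598g0060 fell from 94.9 ± 13.2 to 56.4 ± 2.83 FPKM. Of 257 heat shock genes 25 rose and 27 fell as deposited (30 and 31 adjusted over the list alone), and 39 rose and 20 fell after quantile normalization. The list lay above the other genes (camera adjusted p = 0.00578; adjusted p = 0.978 with an estimated correlation) and missed in 1 of 15 other settings, without the filter (0.0742). HSP70 chaperones had 9 higher and 6 lower of 43 (camera adjusted p = 0.00587; adjusted p = 0.713 with an estimated correlation). In the HSP90 list, which also holds activators of the HSP90 ATPase, 4 of 21 genes rose and 3 fell (6 and 2 after quantile normalization), 1 of these the activator Nitab4.5_0000019g0070 (camera adjusted p = 0.0217; adjusted p = 0.732 with an estimated correlation). Their list passed in 12 of 15 other settings, and missed after quantile normalization (0.0614) and without GDH64 library 3 (0.092). Heat shock factors had 4 higher and 1 lower of 38, against 6 and 1 after quantile normalization (camera adjusted p = 0.0254; adjusted p = 0.696 with an estimated correlation), with Nitab4.5_0000586g0140 up from 1.06 ± 0.0643 to 6.33 ± 1.62 FPKM. Their list passed in 7 of 15 other settings (adjusted p from 0.0162 to 0.26). It missed after quantile normalization (0.059) and without GDH64 library 2 (0.0672), MuGDH64 library 2 (0.0948) or MuGDH64 library 3 (0.0813). Small heat shock proteins had 2 higher and 11 lower of 69 as deposited and 7 and 5 after quantile normalization (camera adjusted p = 0.525).

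Among antioxidant enzymes the ascorbate peroxidase Nitab4.5_0008525g0010 fell from 90.1 ± 4.11 to 34.4 ± 4.35 FPKM and the catalase Nitab4.5_0009821g0010 from 697 ± 57.1 to 359 ± 31.03 FPKM. The antioxidant list of 59 genes had 5 higher and 5 lower (6 and 7 adjusted over the list alone, 8 and 5 after quantile normalization) and lay above the other genes (camera adjusted p = 0.00418; adjusted p = 0.978 with an estimated correlation). Glutathione transferases had 9 higher and 13 lower of 91 as deposited (9 and 20 adjusted over the list alone; camera adjusted p = 0.417) and 11 and 7 after quantile normalization. One of them, Nitab4.5_0008292g0020, rose from 1.11 ± 0.381 to 4.47 ± 1.46 FPKM. Metallothioneins had 4 lower and none higher of 6 (camera adjusted p = 0.0824).

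The cell wall list did not differ from the other genes past the threshold (camera adjusted p = 0.776). Of 175 genes 11 were higher and 36 lower as deposited (15 and 45 adjusted over the list alone), against 16 and 28 after quantile normalization. A pectinesterase, Nitab4.5_0001544g0040, fell from 31.1 ± 2.88 to 13.4 ± 1.14 FPKM. The xyloglucan endotransglucosylase Nitab4.5_0013465g0010 rose from 170.0 ± 28.7 to 335 ± 10.8 FPKM, and Nitab4.5_0001134g0070 of the same family fell from 115 ± 1.53 to 56.6 ± 6.597 FPKM. That family had 6 higher and 7 lower of 31 as deposited and 8 and 5 after quantile normalization (camera adjusted p = 0.00551; adjusted p = 0.696 with an estimated correlation). Its list passed in 12 of 15 other settings (adjusted p up to 0.105), and missed after quantile normalization (0.0614). Expansins had 1 higher and 1 lower of 22, against 3 and 1 after quantile normalization (camera adjusted p = 0.0392; adjusted p = 0.696 with an estimated correlation). Their list passed in only 6 of 15 other settings (adjusted p from 0.0191 to 0.399). It missed after quantile normalization (0.164) and without GDH64 library 1 (0.0595), GDH64 library 3 (0.0868) or MuGDH64 library 3 (0.0512). Cellulose synthases had 2 higher and 8 lower of 25 (camera adjusted p = 0.596).

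Genes of cell division and DNA repair, a question raised by the irradiation, gave few calls. Of 165 cell cycle genes 2 rose and 11 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.93), against 5 and 6 after quantile normalization. Of 93 DNA repair genes 6 fell and none rose (2 adjusted over the list alone; camera adjusted p = 0.93), against 4 higher and 3 lower after quantile normalization. Core histones had 2 higher and 3 lower of 77 as deposited and 5 and 2 after quantile normalization (camera adjusted p = 0.00587; adjusted p = 0.723 with an estimated correlation). Their list passed in 11 of 15 other settings, and missed after quantile normalization (0.12) and without GDH64 library 2 (0.11). Transposon proteins had 1 higher and 7 lower of 109 as deposited and 3 and 2 after quantile normalization (camera adjusted p = 0.961).

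Ribosomal proteins of the eukaryotic families lay above the other genes as a group of 274, with 15 higher and 9 lower as deposited (camera adjusted p = 7.9e-13; adjusted p = 0.696 with an estimated correlation). The counts were 42 and 3 after quantile normalization, and 0 and 0 adjusted over the list alone. The cytosolic ribosome list of 12 had 0 genes past the threshold, also adjusted over the list alone (camera adjusted p = 0.0465; adjusted p = 0.978 with an estimated correlation). It passed in 9 of 15 other settings (adjusted p from 0.00363 to 0.219), and missed without GDH64 library 2 (0.0517), GDH64 library 3 (0.202) or MuGDH64 library 1 (0.219). Families of short proteins lay 0.147 above families of long proteins in median log2 change (95% bootstrap interval 0.115 to 0.192, 281 and 215 genes). The interval comes from resampling genes, which are not independent, with the 6 libraries held fixed. It does not measure the spread between libraries. This difference stands beside the ribosomal, histone, Rubisco small subunit, CAP and Bet v I groups, which are short proteins. Other short proteins lay on the other side without passing, with medians of -0.33 for metallothioneins and -0.13 for lipid transfer proteins relative to all genes.

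The vein list and the flower and apex list did not differ from the other genes past the threshold. The vein list had none higher and 3 lower of 38 as deposited (3 adjusted over the list alone; camera adjusted p = 0.582) and 3 higher and 2 lower after quantile normalization. A phloem protein 2-like gene, Nitab4.5_0000140g0190, fell from 73.3 ± 12.3 to 38.2 ± 5.14 FPKM. The flower and apex list, which also catches pollen Ole e 1 domain proteins found in leaves, had 2 higher and 9 lower of 59 (3 and 11 adjusted over the list alone; camera adjusted p = 0.93). One of these, Nitab4.5_0000194g0060, rose from 16.6 ± 4.86 to 54.7 ± 6.31 FPKM. Lists for trichome regulators, trichome products and guard cells matched no description and were not analysed here. Mean, median and test differed in sign for the pathogenesis-related, jasmonate, ethylene, abscisic acid, vein, flower and cell cycle lists, none of which passed. The same held for the domain lists of peroxidases, NAC factors, jasmonate proteins, gamma thionins, serine protease inhibitors, UDP-glycosyltransferases, small heat shock proteins and transposons. Of the 182 genes named by the rule, 172 passed with the same sign after quantile normalization.

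**Figure D3:**
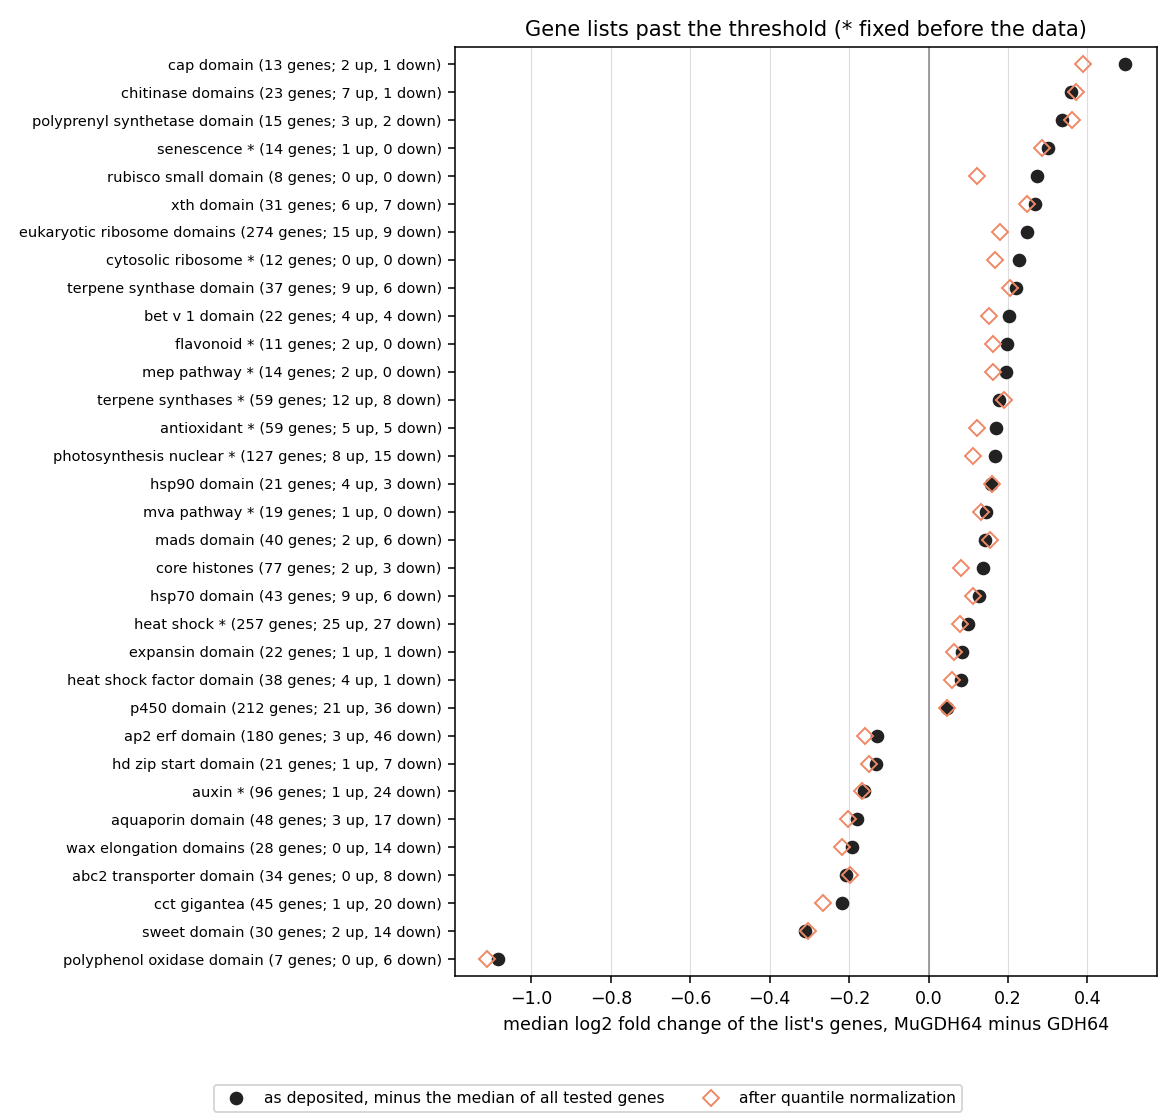
The 33 gene lists past the threshold of camera with a preset correlation, with the median log2 fold change of their genes (MuGDH64 minus GDH64) on the horizontal axis: filled circles as deposited minus the median of all tested genes, diamonds after quantile normalization, an asterisk for lists fixed before the data were examined. All 33 medians keep their side of 0 between these scalings, from -1.085 for polyphenol oxidases to 0.495 for CAP proteins. Both scalings take out the shift of all genes between the lines, so this is no test of that shift. With an estimated correlation 0 lists passed.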

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

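Median-centring and library weights were chosen after the data had been seen, and the other alternatives before; those meant for NtCYC and the cembranoid list were not run, because the list matched no gene. Of 3863 genes (712 higher, 3151 lower, 644 at least 2-fold), quantile normalization gave 1433 higher and 1671 lower, median-centring 1940 and 1384, and rescaling to 1000000 per library 1285 higher, settings that remove the shift between the lines in whole or part by construction. No filter gave 2280 genes, 1784 lower, with more genes in the adjustment. A filter of 5 FPKM left 400 genes with at least 2-fold change among fewer tested, and a pseudocount of 0.1, which widens low-value changes by construction, gave 1058. Library weights, with GDH64 library 2 at 0.51 and library 1 at 2.64, gave 6284 genes, 1266 higher and 5018 lower; the cause was not tested. Fits without 1 library had fewer samples by construction. They gave 1794 to 3141 genes, 348 to 650 higher, 1345 to 2491 lower, 491 to 691 at least 2-fold, and 26 to 31 lists. A named gene that no longer had at least 1 FPKM in 3 libraries was not tested in such a fit. Of the named genes still tested, 21, 15 and 9 lost their call without GDH64 libraries 1, 2 and 3. Without MuGDH64 libraries 1, 2 and 3 the losses were 15, 17 and 18, and no tested gene changed sign. Deviations of libraries with the same number were nearly unrelated (r across genes 0.015, 0.013 and 0.051). Between libraries with different numbers r lay from -0.046 to 0.028. No strong shared effect of the number was seen, but this cannot show whether the numbers mark field blocks. With a replicate block 3991 genes, 652 of them at least 2-fold, and 33 lists passed. The homeobox list lost its call (camera adjusted p = 0.0501), and 3 of the 188 named genes lost theirs. Which other genes lost a call was not counted.

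Of the 33 lists past camera, 0 passed with an estimated correlation, and the cause was not tested. Of all tested lists 13 passed fry, which tests a mean against 0 and not against other genes, and 8 of these are among the 33. By fry 8 list directions were reversed, none past the threshold: photosynthesis (mean -0.034, adjusted p = 0.602), antioxidant (-0.016, 0.792), heat shock (-0.049, 0.625), P450 (-0.066, 0.226), core histones (0.037, 0.813), expansin (-0.012, 0.872), xyloglucan endotransglucosylase (0, 0.991) and MADS-box (-0.006, 0.382), the core histone direction being that of fry's test and not of its mean. Of the 33 lists 23 kept their call after quantile normalization, 25 with median-centring, 25 with library weights, 23 without the filter, 23 with a filter of 5 FPKM, 32 without the trend, 29 after rescaling and 33 with a pseudocount of 0.1. Of 188 named genes, the 6 chosen after their values were seen included, quantile normalization ended 10 calls, no filter 17, median-centring 17, rescaling 4, the block 3, no trend 2, a pseudocount of 0.1 ended 1 and library weights 0. Depth is unknown, so counting error in genes of low value could not be set apart.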

Other observations

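The tests of the shift that abundant genes give, of deletions spanning neighbours, of tandem copies, of reads moved between models and of neighbouring terpene synthase and P450 genes were chosen after results they bear on had been seen, and the others were written down before their values were measured, after the fits had been seen. Earlier tests were replaced for abundant genes, where the share of the top 100 parted the groups by 0.23 percentage points, for moved reads, where 9 of the 24 most changed genes had a partner, and for deletions and tandem copies, which rested on neighbouring pairs. In all, 9 explanations and the splits of the libraries for 3 counts were tested.

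A pair of terpene synthases, chosen after their values were seen, lie near a P450 gene on the same scaffold and rose together with it, if gene numbers follow the order on a scaffold. Nitab4.5_0001461g0050 rose from 2.73 ± 0.767 to 13.2 ± 1.35 FPKM and the P450 gene Nitab4.5_0001461g0070 from 2.20 ± 0.148 to 5.82 ± 0.356 FPKM (mean ± SD, n = 3 libraries per line). Nitab4.5_0002717g0050 rose from 4.45 ± 0.333 to 19.2 ± 2.62 FPKM and the P450 gene Nitab4.5_0002717g0030 from 0.197 ± 0.1002 to 1.98 ± 0.461 FPKM. A further terpene synthase, Nitab4.5_0002485g0020, next to Nitab4.5_0002485g0030, rose from 0.347 ± 0.0808 to 3.36 ± 0.207 FPKM. Both of the 2 measured pairs within 3 models were higher, where shuffled P450 calls gave a mean of 0.19 (permutation p = 0.0086). As 2 pairs are few, a limit set after this p was seen, and the pattern was noticed in these pairs, raised expression of terpene gene clusters in MuGDH64 is a hypothesis that this test cannot settle.

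The 1st pattern weighed is the excess of lower over higher genes. Scaling cannot be told apart from a lower output of many genes in MuGDH64: higher genes made up 46.2% of calls after quantile normalization, which removes a shift whatever its source, and 36.4% after rescaling to one total, a share looked at after the results had been seen. A larger share for a few abundant genes is argued against as the whole cause: the 100 most abundant genes held more of the summed FPKM in every MuGDH64 library, but their mean shares of 16.74% and 17.49% lower the other genes by a log2 shift of only -0.013, where the median was -0.176. Short-protein families lay 0.147 above long ones, as a difference in transcript length or RNA integrity would give, although the short metallothioneins had a median of -0.33 relative to all genes. The medians were -0.054 for the short and -0.201 for the long families, before the subtraction of the median of all genes. The long families thus lay close to the -0.176 of all genes. A lower output of many genes was not tested and stays open.

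The 2nd pattern is the set of 19 genes with at least 1 FPKM in every GDH64 library and at most 0.1 FPKM in every MuGDH64 library; 15 genes showed the opposite, 78.9% of that number, among them the undescribed Nitab4.5_0003395g0040, singled out after its values were seen, at 18.5, 19.75 and 14.4 FPKM in MuGDH64 and listed at 0 in GDH64. The tables argue against deletions spanning neighbouring genes, and against tandem copies silent together, for most genes of the set with an expressed neighbour. This holds if gene numbers follow the order on a scaffold. The set holds 0 neighbouring pairs, and 0 of 35 expressed neighbours were silent in MuGDH64, an upper 95% Clopper-Pearson limit of 10%. This limit takes the neighbours as independent, although those of the same gene would share a deletion, so it may be too low. It bounds a share of neighbours and not of the 19 genes. How many of the 19 have no expressed neighbour was not counted. The log2 changes of these neighbours had a median of -0.23 and a lowest value of -1.35, before the subtraction of the median of all genes. Deletions that leave reads of a near-identical copy on a neighbour are not covered. Genes that fell without reaching 0.1 FPKM lie outside the set and were not weighed. Among them are the NB-ARC genes Nitab4.5_0001553g0040 and Nitab4.5_0001553g0060 of the same scaffold, at means of 0.567 and 0.743 FPKM in MuGDH64. The count of neighbours follows from that of the pairs (permutation p = 1), which was seen first, and the bound of 20% was set after it, while deletions of single genes stay open. Reads moved between models with the same domains cannot be told apart from other causes, as 5 of the 12 silent genes with a described domain had such a partner moved the other way, where domain groups of random genes gave a mean of 4.17 (permutation p = 0.41). Genetic differences between the lines in both directions also stay open, since the test needed neighbouring pairs.

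The 3rd pattern is the fall of CCT domain genes. In their list with GIGANTEA 20 of 45 genes fell and 1 rose, against 13 and 1 after quantile normalization. The list did not pass camera with an estimated correlation (adjusted p = 0.696). A different time of day at sampling cannot be told apart from other causes: the 4 GIGANTEA models went both ways, with a median log2 fold change of -0.18 before the subtraction of the median of all genes. The rule written beforehand, an absolute median under 0.5, was met and would have counted against a different time of day. The verdict was left open after the median had been seen, because the median lies nearer to 0.5 than the models' SD of 0.34. The median of all tested genes was close to it, at -0.176. A difference in developmental stage between the lines was not tested and stays open.

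The splits of the 6 libraries into 3 and 3 number 10, so their share cannot go under 0.1. The real split gave 3863 genes, where the highest other split gave 2, and 644 genes with at least 2-fold change, where the highest other gave 2. It gave 33 lists, where the highest other gave 15. In each case 1 of 10 splits gave as many. Every other split mixes the lines, so the difference between the lines widens the spread within its groups. Low gene counts there are built in and are no measure of chance. The split with 15 lists past camera with the preset correlation had 0 genes past the threshold.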
